A study of Mus musculus with 9 samples.

How the data were processed

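Total RNA of mouse epididymal fat, a visceral fat depot beside the epididymis, was measured on 9 single-colour Illumina bead arrays. Per the labels, the C57BL6/J mice were 16 weeks old and were weaned onto a normal diet (ND), a high fat diet (HFD) or a high fat diet with 2% mannose in the drinking water (HFDM), with 3 mice per group. Groups and replicate numbers were taken from the sample titles. The design text speaks of 3 mice each, so each array was read as 1 mouse.

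The deposited non-normalized table holds an average signal intensity and a detection p-value for each of 45281 probes on each array, per the file headers. The detection p-value states how a probe's signal ranks against the negative control beads. The submitters' processing notes name GenomeStudio, and its version is not given in the sources used here. The deposited signals are already background subtracted to some degree, since 27.3 to 33.2% of the values per array are negative. The authors also deposited a second table of processed intensity values for the same arrays. These values are on a linear scale with a median of 155.4 on every array and follow the order of the signals of the same array (Spearman's rho of 1). How the authors normalized them is not given in the sources used here, and this table served only as an alternative.

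The signals were corrected for background with limma 3.58.1 in R 4.3.3, by the normal-exponential model with negative controls inferred from the detection p-values and an offset of 16. The log2 values were then quantile normalized. Probes were kept when their detection p was under 0.05 on at least 3 of the 9 arrays, which left 20772 probes. Gene symbols came from the platform annotation and were updated by gene identifier to RefSeq's mouse gene table (assembly GRCm38.p6). Of all probes, 34885 had 1 symbol, 18 had several and 10378 had none here. Of the probes with 1 symbol, 34807 matched that gene table. For each gene the probe with the highest mean over all arrays was used, and probes without a single symbol stayed as separate features that are never named. This gave 14711 features, of which 11649 were named genes and 3062 were unnamed probes. All are called genes in the counts.

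Each comparison was tested with limma's linear model with all 3 groups in the fit, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over all 14711 features. Tests were two-sided and a gene was called at an adjusted p under 0.05. Values are normalized log2 signals as mean ± SD over 3 arrays, and log2 fold changes carry the standard error (SE) of the model. Where a probe was below detection on all arrays of a group, the change is given as "at least N-fold". It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. The number of arrays limits the precision: the median SE over all genes was 0.275. P-values measure the spread between these mice only. Probe agreement was counted once per comparison, for called genes named for their large change or named wherever measured. Of these, 17 had another detected probe, and for 14 of them every other probe had the same sign. Genes named only through a list are not in this count.

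Before the data were examined, 32 gene lists, the tests of genes and lists, the alternatives and the rule for named genes were fixed. Several tests of explanations were chosen or extended after results had been seen, as stated under the other observations. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 96 tests of 32 lists in 3 comparisons. Named genes are, per comparison, up to 12 higher and 12 lower with the largest change among called genes whose arrays do not overlap between groups. Where fewer than 4 pass, the 4 with the smallest p are given as values that did not pass. Up to 3 genes with the smallest p from each list described follow. Lep, Adipoq, Pparg, Mest, Sfrp5, Npr3, Cd68, Itgax, Ccl2, Tnf, Fasn, Scd1, Ucp1 and Mpi are named wherever measured. No unnamed or clone-named probe is named.

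The HFD arrays enter both HFD vs ND and HFDM vs HFD, which gives opposite fold changes by chance alone. The covariance of the fold changes was therefore set against that of 100 simulated experiments without effects and against the value expected from the residual variance. Genes were also called without 1 HFD array and read in HFDM minus that array. Alternatives covered normalization, offset, filter, probe rule, variance model, arrays in the fit, the replicate number as a block, threshold, set test and leaving out each array. Alternatives that treat sperm and testis transcripts were added after the data were seen.

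The procedure was tested on simulated data for HFD vs ND, with 14711 genes, 200 changed genes and 20 simulations. It found 27.1% of genes changed 2-fold and 84.2% of genes changed 4-fold, with 5.5% false calls. The simulated covariance was -0.0272 and the recovered one was -0.0285. A simulated list shift of 0.5 was found in 20 of 20 simulations. The simulation drew genes independently, unlike real genes.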

Results

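Gene expression was profiled in epididymal fat of 9 mice, 3 each on ND, HFD and HFDM. Between 18390 and 20903 probes per array were above the negative controls, and the median signal was 16.65 to 26.45 units. The comparisons ask what the high fat diet changes in this fat depot and whether mannose in the water alters that response. Arrays correlated at r = 0.878 to 0.984 within groups and at 0.858 to 0.977 between groups, computed across genes, which are not independent replicates. No array duplicated another.

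Transcripts of sperm and testis differed between arrays of the same group. The protamine gene Prm1, which packs DNA in sperm, had a log2 signal of 14.75 on ND 2, 13.34 on ND 3, 14.51 on HFD 3, 15.63 on HFDM 1 and 14.55 on HFDM 3. On the other 4 arrays it was 9.43 (ND 1), 7.69 (HFD 1), 7.07 (HFD 2) and 8.42 (HFDM 2). The mean of 8 such markers ranged over 7.12 log2 units within a group, while group means differed by at most 2.75. On the first principal component, with 51.1% of the variance, the 5 arrays with high Prm1 lay at -9.7 to 92.9 and the other 4 at -54.2 to -36.6. The epididymal gene Lcn8, a lipocalin, was at 12.66 on ND 3 and at 5.38 to 6.16 on the other 8 arrays, while other epididymal markers were also raised elsewhere, such as Adam7 at 7.82 on ND 1 and Cst12 at 8.59 on HFDM 1.

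**Figure D1:**
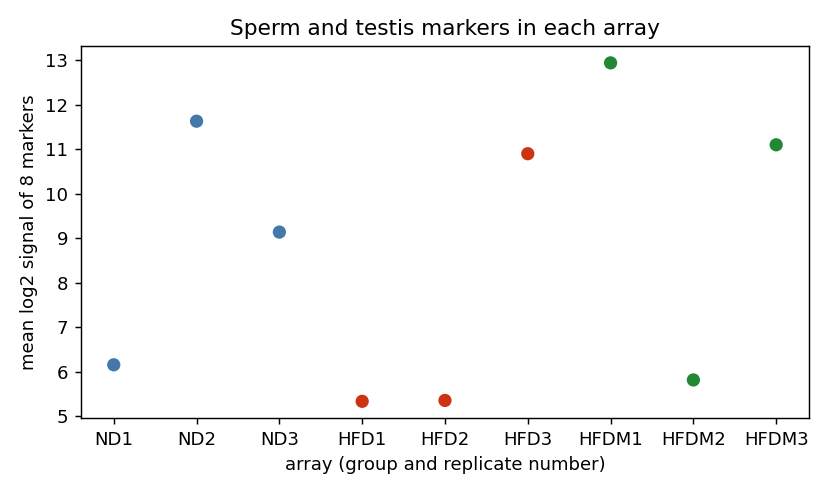
Mean normalized log2 signal of 8 sperm and testis markers (vertical axis) in each of the 9 arrays (horizontal axis), coloured by group. 5 arrays lie between 9.14 and 12.94 and 4 arrays between 5.34 and 6.16, and each group holds arrays of both kinds.

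In epididymal fat, genes of macrophages, inflammation and lysosomes were higher and genes of fatty acid synthesis were lower in HFD than in ND (camera at the preset correlation, with adjusted p = 0.22, 0.43, 0.25 and 0.52 with an estimated correlation). Saa3, an acute phase protein, rose from 8.30 ± 0.38 in ND to 12.74 ± 0.67 in HFD (SD, n = 3 each), a log2 change of 4.44 ± 0.33 (SE, limma adjusted p = 0.00047). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 3.95 ± 0.45, and Mmp12, macrophage elastase, by 3.78 ± 0.58. In the other direction, Cyp2f2, a cytochrome P450 enzyme, fell from 11.03 ± 0.34 to 7.39 ± 0.42, a log2 change of -3.64 ± 0.27. In all, 298 genes were higher and 107 were lower in HFD than in ND. In all 405 genes the 3 arrays of one group lay beyond the 3 of the other, as did 21.1% of all genes tested, where chance gives about 10% for 3 arrays against 3.

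The largest increases were those of Ubd, a ubiquitin-like protein induced by cytokines (5.27 ± 0.56), and Tph2, an enzyme of serotonin synthesis (5.07 ± 0.59). Slc5a7, a choline transporter, rose by 4.85 ± 0.38, Rgs1 by 4.46 ± 0.32, Lipf, a lipase, by 4.26 ± 0.48, and Pvalb, a calcium-binding protein, by 4.24 ± 0.40. Vsig8 was below detection on all 3 ND arrays and at least 10.5-fold higher in HFD. Rnase2a (3.89 ± 0.84) and Ct55 (3.76 ± 0.40) complete the 12 largest increases. Acsm3, a medium-chain acyl-CoA synthetase, changed by -3.83 ± 0.59, Adgrg2 by -2.18 ± 0.40, Tst by -2.17 ± 0.32, Thbd, thrombomodulin, by -2.13 ± 0.42, and Ces1f, a carboxylesterase, by -2.09 ± 0.35. Wfdc15b was below detection in HFD and at least 4.38-fold lower there. Tmem79, Steap2, Cacna1d, Phkg1 and Nat8l changed by -2.01 to -1.82. Of the other named probes of these genes, that of Cacna1d (0.33) and 1 of Acsm3 (0.08) did not go down.

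Macrophage genes rose as a list, with 8 of 25 measured members higher and none lower (17 higher adjusted over the list alone, mean log2 change 1.18, camera adjusted p = 7e-14, adjusted p = 0.22 with an estimated correlation). Besides Gpnmb, these included Trem2, a lipid-sensing receptor (2.95 ± 0.39), and Cd84 (1.74 ± 0.21). Of 19 inflammatory cytokine and chemokine genes, 8 rose, 14 adjusted over the list alone (mean 1.43, camera adjusted p = 7.6e-13, adjusted p = 0.43 with an estimated correlation). Ccl2, which attracts monocytes, rose by 3.04 ± 0.44 and Il1rn, the interleukin receptor antagonist, by 2.54 ± 0.35. Lysosomal genes rose in 7 of 26 members, 13 adjusted over the list alone (mean 0.59, camera adjusted p = 6.1e-10, adjusted p = 0.25 with an estimated correlation). The smallest p were those of Ctsa (1.30 ± 0.14), Lipa, lysosomal acid lipase (1.15 ± 0.16), and Glb1 (1.21 ± 0.21). Of 14 genes of MHC class II presentation, 5 rose, 8 adjusted over the list alone (mean 0.65, camera adjusted p = 4.8e-07, adjusted p = 0.52 with an estimated correlation). They were H2-DMb1 (1.34 ± 0.19), Ifi30 (1.48 ± 0.31), Cd74 (0.74 ± 0.16) and, named after their values were seen to complete the count, H2-Ab1 and H2-DMb2.

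Among 31 collagen and matrix genes, 5 rose and 1 fell, 12 and 1 adjusted over the list alone (mean 0.51, camera adjusted p = 8.4e-07, adjusted p = 0.49 with an estimated correlation). Col4a2 rose by 1.08 ± 0.18, Tnc, tenascin, by 1.27 ± 0.22 and Col18a1 by 0.91 ± 0.16. Col6a2 and Thbs2 also rose and Mmp9 fell, which are named after their values were seen. The adipose expansion list rose with 3 of 12 members (5 higher and 2 lower adjusted over the list alone, mean 0.69, camera adjusted p = 0.0093, adjusted p = 0.59 with an estimated correlation). Mest rose by 1.74 ± 0.27 and Sfrp5, a secreted Wnt inhibitor, by 2.90 ± 0.41, and the third was Trem2, which is also in the macrophage list. Immediate early genes rose in 2 of 17 members, 3 adjusted over the list alone (mean 0.55, camera adjusted p = 0.00058, adjusted p = 0.51 with an estimated correlation), Junb by 1.27 ± 0.18 and Fos by 1.86 ± 0.35. Neutrophil markers rose in 2 of 5 members, both also adjusted over the list alone (mean 1.12, camera adjusted p = 0.021, adjusted p = 0.67 with an estimated correlation), S100a8 by 3.68 ± 0.66 and Il1r2, below detection in ND, at least 1.75-fold. The cell cycle list was higher with 0 of 20 members called, 3 adjusted over the list alone (mean 0.65, camera adjusted p = 0.00017, adjusted p = 0.60 with an estimated correlation). Its smallest p was that of Tk1 (1.85 ± 0.43, adjusted p = 0.059). Single arrays decided 2 of these calls: the expansion list had adjusted p = 0.0881 without ND 1 and likewise without HFD 1, and the neutrophil list had adjusted p = 0.0532 without ND 2, 0.127 without ND 3 and 0.148 without HFD 1, with means of 2.28 without ND 1 and 1.89 without HFD 2.

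Fatty acid and triglyceride synthesis fell with 3 of 23 members, 9 adjusted over the list alone (mean -0.68, camera adjusted p = 2.5e-07, adjusted p = 0.52 with an estimated correlation). Fads1, a fatty acid desaturase, changed by -1.36 ± 0.14, Tkt, transketolase, by -1.25 ± 0.21 and Acacb, an acetyl-CoA carboxylase, by -1.46 ± 0.25. The branched-chain amino acid breakdown list was lower with 0 of 18 members called, 8 adjusted over the list alone (mean -0.53, camera adjusted p = 1e-06, adjusted p = 0.54 with an estimated correlation), with Echs1 at -0.70 ± 0.16 and Ivd at -1.03 ± 0.24. The oxidative phosphorylation list was lower with 1 of 43 members called, also adjusted over the list alone (mean -0.21, camera adjusted p = 0.0051, adjusted p = 0.76 with an estimated correlation), namely Atp5c1 (-0.79 ± 0.13). Without ND 1 the mean of this list was -0.083 (adjusted p = 0.305), and without ND 2 it was -0.33. The remaining 20 lists, among them markers of endothelium, mast cells, progenitors, mesothelium, B cells, T cells and red blood cells, were not called. Sperm and testis markers had a mean of -1.77 (camera adjusted p = 0.27) and epididymal markers of -1.55 (camera adjusted p = 0.066), both lower in HFD on average. The former was -3.18 without ND 1, -0.44 without ND 2, -0.84 without HFD 1, -0.86 without HFD 2 and -3.65 without HFD 3 (adjusted p = 0.00471), and the latter -2.25 without ND 2 (adjusted p = 0.00524) and -0.35 without ND 3.

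Lep, Adipoq and Scd1 lay above the 99.8th percentile of every array, near the top of the measured range, with log2 changes of 0.14, -0.17 and -0.01. Pparg (-0.37 ± 0.30), Npr3 (0.30 ± 0.19), Fasn (-0.72 ± 0.35) and Mpi, which converts mannose phosphate to fructose phosphate (0.01 ± 0.24), did not pass. The Fasn probe was dim, at log2 signals of 6.54 to 8.60 over all arrays, where the lowest detected signals were 5.487 to 5.805. Its values in all comparisons are limited by this. No probe named here measures Cd68, and Itgax and Tnf were not detected on enough arrays to be tested. The count rests on each HFD array: it was 42 higher and 11 lower without HFD 2, 76 and 26 without HFD 1, 93 and 23 without HFD 3, 158 and 49 without ND 2, 353 and 169 without ND 1, and 209 and 60 without HFDM 3. Without ND 2 and HFDM 1, which had the highest testis marker means, it was 153 and 53, and with the testis marker mean as a covariate 307 and 147.

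**Figure D2:**
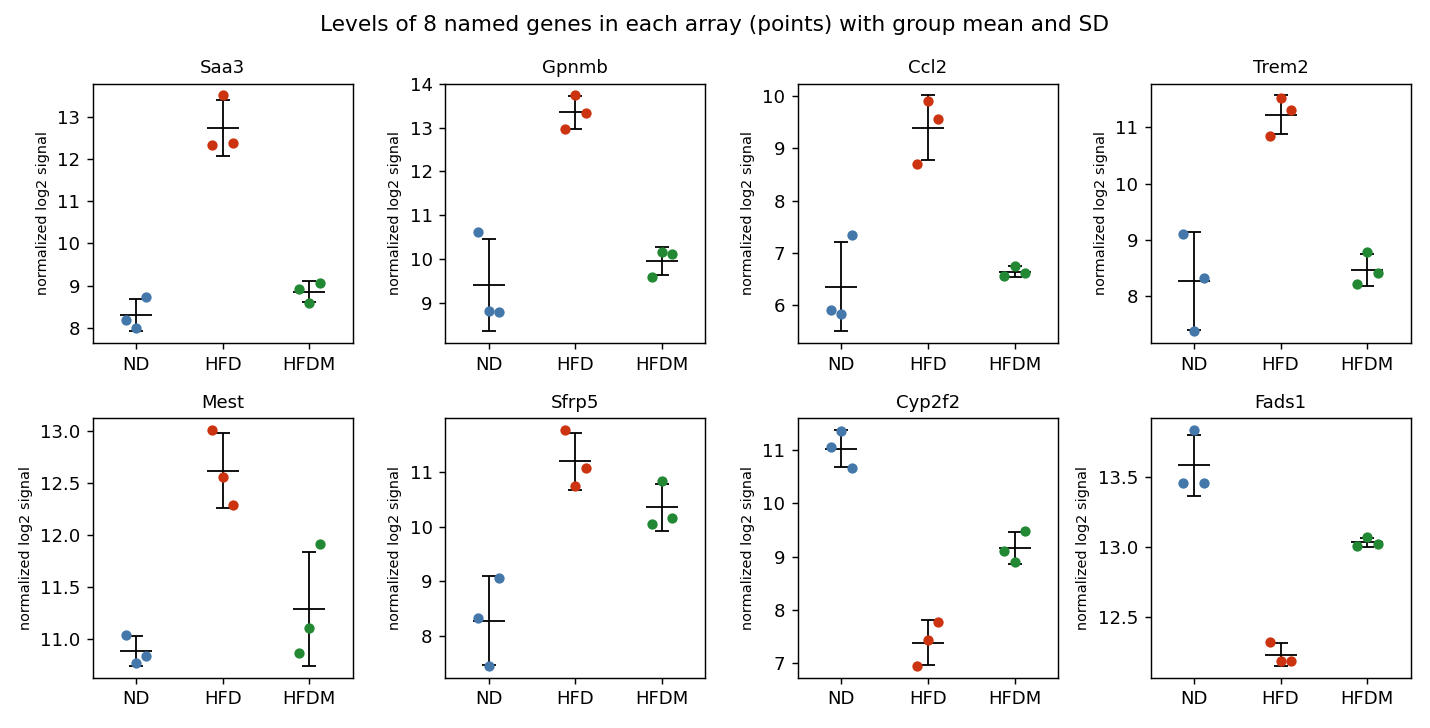
Normalized log2 signal (vertical axes) of 8 named genes in ND, HFD and HFDM, with 1 point per array and the group mean and SD as bars. Saa3 averages 8.30 in ND, 12.74 in HFD and 8.86 in HFDM, and Cyp2f2 averages 11.03, 7.39 and 9.16.

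With mannose in the water, most genes called under the high fat diet stood closer to the ND level. Saa3 fell from 12.74 ± 0.67 in HFD to 8.86 ± 0.25 in HFDM (SD, n = 3 each), a log2 change of -3.88 ± 0.33 (SE, limma adjusted p = 0.002), and Gpnmb changed by -3.40 ± 0.45 and Mmp12 by -3.51 ± 0.58. Ccl2 changed by -2.76 ± 0.44. Acsm3 rose by 3.46 ± 0.59 and Cyp2f2 by 1.78 ± 0.27. In all, 26 genes were higher and 176 were lower in HFDM than in HFD. This comparison is itself the test of the difference between the effects of HFD and HFDM against ND. All 202 genes had non-overlapping arrays, as did 23.7% of all genes.

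Tph2 (-5.13 ± 0.59) and Ubd (-4.75 ± 0.56) had the largest decreases. Rgs1 and Vsig8 were below detection on all HFDM arrays and at least 20.1-fold and 10.3-fold lower. Pvalb changed by -3.65 ± 0.40, Sirpb1a by -3.17 ± 0.43, Lipf by -2.93 ± 0.48 and Nup210, a nuclear pore protein, by -2.86 ± 0.24. Among the genes that rose were Pde1a, a phosphodiesterase (1.82 ± 0.32), Fign (1.63 ± 0.33), Rasgrf1 (1.57 ± 0.30), Cenpv (1.46 ± 0.28) and Steap2 (1.38 ± 0.28). Pdlim3, Snhg11, Vnn3, Gsta3, a glutathione transferase, and Slc2a13 rose by 1.37 to 1.15.

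Macrophage genes fell in 8 of 25 members, 17 adjusted over the list alone (mean -1.15, camera adjusted p = 2.8e-15, adjusted p = 0.22 with an estimated correlation). Cd84 changed by -1.65 ± 0.21, Trem2 by -2.75 ± 0.39 and Adgre1, the F4/80 antigen, by -1.07 ± 0.15. Inflammatory genes fell in 7 of 19 members, 16 adjusted over the list alone (mean -1.42, camera adjusted p = 2.4e-14, adjusted p = 0.40 with an estimated correlation), with Il1rn at -2.23 ± 0.35. Lysosomal genes fell in 2 of 26 members, 16 adjusted over the list alone (mean -0.60, camera adjusted p = 7.8e-12, adjusted p = 0.22 with an estimated correlation). They were Lipa (-1.26 ± 0.16) and Ctsa (-0.94 ± 0.14). MHC class II genes fell in 4 of 14 members, 8 adjusted over the list alone (mean -0.73, camera adjusted p = 1.5e-08, adjusted p = 0.49 with an estimated correlation). They were H2-DMb1 (-1.24 ± 0.19), Ifi30 (-1.55 ± 0.31), H2-Eb1 (-0.80 ± 0.16) and, named after its value was seen, H2-DMb2.

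Immediate early genes fell in 2 of 17 members, 5 adjusted over the list alone (mean -0.50, camera adjusted p = 0.0051, adjusted p = 0.59 with an estimated correlation), Junb by -1.25 ± 0.18 and Egr2 by -1.86 ± 0.36. The cell cycle list fell with Tk1 called (-2.23 ± 0.43), 1 of 20 members and 3 adjusted over the list alone (mean -0.61, camera adjusted p = 0.00017, adjusted p = 0.60 with an estimated correlation). Neutrophil markers fell with Il1r2 called (below detection in HFDM and at least 1.72-fold lower), 1 of 5 members and 2 adjusted over the list alone (mean -1.07, camera adjusted p = 0.015, adjusted p = 0.65 with an estimated correlation). Collagens and matrix genes were lower as a list with none of 31 called, 2 adjusted over the list alone (mean -0.32, camera adjusted p = 0.0039, adjusted p = 0.65 with an estimated correlation), with Col6a2 at -1.02 ± 0.24. T and natural killer cell markers had a mean of -0.41 with 0 of 10 called and 2 lower adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.51 with an estimated correlation), with Cd8b1 at -0.45 ± 0.13. Cholesterol synthesis had a mean of -0.36 with 0 of 18 called and 0 adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.76 with an estimated correlation), with Lss at -0.78 ± 0.31. Branched-chain amino acid breakdown (mean 0.33, 0 of 18 called, camera adjusted p = 0.00013) and oxidative phosphorylation (mean 0.20, 0 of 43 called, camera adjusted p = 0.00034) were higher, with 0 adjusted over the list alone in each. With an estimated correlation their adjusted p = 0.60 and 0.76, and Ivd stood at 0.75 ± 0.24. Without HFDM 3, whose brown and beige adipocyte list averaged 9.6 against 7.68 and 7.74 on HFDM 2 and HFDM 1, the oxidative phosphorylation mean was 0.07 (adjusted p = 0.102). Fads1 rose by 0.81 ± 0.14, the 1 called member of 23 in a lipid synthesis list that was not called. Other calls that ended without 1 array were neutrophils (adjusted p = 0.175 without HFD 1 and 0.121 without HFD 2), T and natural killer cells (0.0625 without HFD 1 and 0.102 without HFDM 3) and cholesterol synthesis (0.0529 without HFDM 1, 0.136 without HFDM 2 and 0.323 without HFD 2, where its mean was -0.168).

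Sperm and testis markers were higher in HFDM beside these lists (mean 2.75, 0 of 8 called and 0 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.76 with an estimated correlation). Their mean was 1.25 without HFDM 1, 1.82 without HFD 1, 1.83 without HFD 2 and 2.18 without HFDM 3, none of them called, and 4.63 without HFD 3 and 4.82 without HFDM 2. The mannose and glycan assembly list was not called (mean -0.11, median -0.03, 0 of 36 called, camera adjusted p = 0.33, with a mean of -0.055 without HFD 2, -0.064 without HFDM 1 and -0.176 without HFDM 2), and Alg1 (-0.72 ± 0.20), Man2b1 (-0.56 ± 0.15) and Mpi (0.17 ± 0.24) did not pass. Mest (-1.33 ± 0.27, adjusted p = 0.053), Sfrp5 (-0.84 ± 0.41), Lep (-0.02), Adipoq (0.18), Scd1 (0.06), Pparg (0.35), Npr3 (-0.01) and Fasn (-0.25) did not pass either. The counts rest on single arrays: they were 0 higher and 4 lower without HFD 2, 0 and 6 without HFD 3, 1 and 16 without HFD 1, 0 and 9 without HFDM 1, 0 and 11 without HFDM 3, and 6 and 77 without HFDM 2, with 66 higher without ND 1, 49 without ND 2 and 16 without ND 3. The 4 genes without HFD 2 were Saa3, Rgs1, Nup210 and Cyp2c23, the last named after its values were seen. Without ND 2 and HFDM 1 the counts were 6 and 51, and with the testis marker covariate 22 and 107.

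Of the 405 genes called in HFD vs ND, 403 (99.5%) had the opposite sign in HFDM vs HFD, the exceptions being Peg3 and Thbs2. Because both comparisons share the HFD arrays, simulated experiments without effects gave 89.5% on average for as many top genes and 93.3% at most. All simulated values in this paragraph come from genes drawn independently, unlike real genes, so their range may be too narrow. With genes called without 1 HFD array and read in HFDM minus that array, 99.1%, 98.4% and 98.5% had the opposite sign. These are 117, 62 and 131 genes, without HFD 1, HFD 2 and HFD 3. The 2 sets of fold changes had a covariance of -0.269 (r = -0.76), against a simulated -0.0822 (r = -0.50) without effects and -0.108 from the residual variance. The difference from the latter was -0.160 and ranged from -0.269 without HFD 3 to -0.0258 without HFD 2. Higher in HFD and lower in HFDM were 150 genes, against 3.6 for independent lists, and lower then higher were 21, against 0.19. Simulated experiments gave 54.2 such genes among as many top genes.

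**Figure D3:**
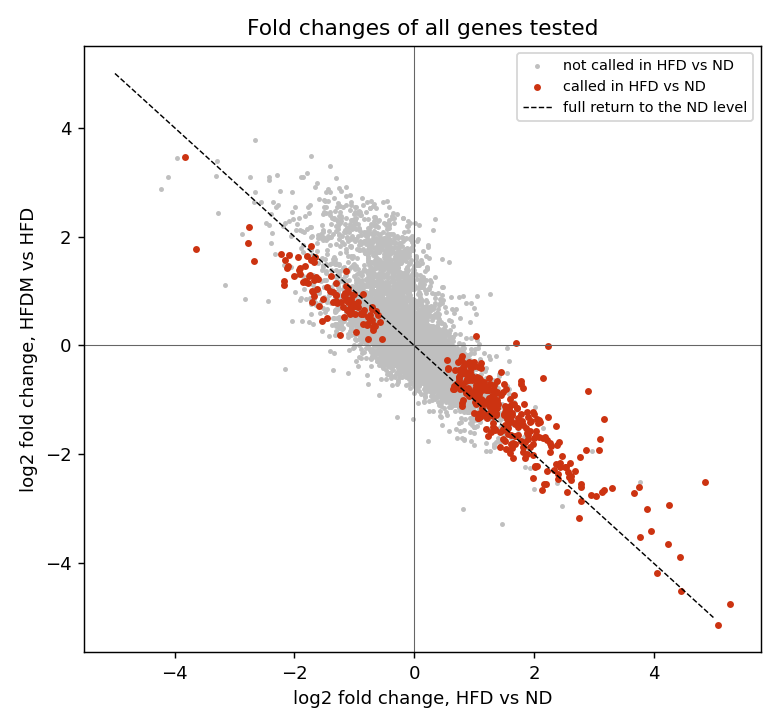
Log2 fold change of HFD vs ND (horizontal axis) against HFDM vs HFD (vertical axis) for each of 14711 genes, with the 405 genes called in HFD vs ND in red and a dashed line for a full return to the ND level. Of the red points, 403 have opposite signs on the axes, and the shared HFD arrays contribute to this tilt.

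The fat of mice given mannose with the high fat diet showed no gene that passed against ND. Slc5a7 (2.34 ± 0.38), Hspb7 (2.22 ± 0.37), Thbs2 (1.21 ± 0.21) and Peg3, an imprinted gene (1.74 ± 0.35), had the smallest p on the higher side and did not pass. On the lower side these were Cyp2f2 (-1.87 ± 0.27), Tkt (-1.06 ± 0.21), Ifrd2 (-1.48 ± 0.31) and Gucd1 (-0.73 ± 0.17). Sfrp5 stood at 2.06 ± 0.41 and Mest at 0.41 ± 0.27. limma called 0 genes, with a smallest adjusted p of 0.776. At an unadjusted p under 0.05 there were 212 higher and 371 lower genes, against 736 in all by chance. A count of 0 does not show that the groups are alike.

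The lipid synthesis list was lower in HFDM than in ND (mean -0.51, 0 of 23 called, 3 lower adjusted over the list alone, camera adjusted p = 3.9e-09, adjusted p = 0.49 with an estimated correlation). Fads1 stood at -0.55 ± 0.14 and Me1 at -0.92 ± 0.26. The adipose expansion list was higher (mean 0.38, 0 of 12 called, 1 adjusted over the list alone, camera adjusted p = 0.00081, adjusted p = 0.49 with an estimated correlation), with Cavin1 at 0.45 ± 0.18. Collagens were higher (mean 0.20, 0 of 31 called, 1 adjusted over the list alone, camera adjusted p = 0.00044, adjusted p = 0.60 with an estimated correlation). Branched-chain amino acid breakdown (mean -0.20), interferon response (mean -0.20) and endothelial markers (mean -0.22) were lower with no member called, also adjusted over the list alone. Their camera adjusted p = 0.04, 0.0051 and 0.012, and with an estimated correlation 0.76, 0.60 and 0.60. Most of these calls rest on single arrays. The amino acid list ran from -0.339 without ND 3 to -0.072 without HFDM 1 and was not called without ND 1, ND 2 (-0.116), HFDM 1 or HFDM 2. The interferon list ran from -0.339 without ND 1 to -0.105 without ND 2 and was not called without ND 2 or HFDM 3. Endothelial markers were not called without ND 2, ND 3 (-0.163) or HFDM 2, the expansion list not without ND 1 (0.309), and collagens not without ND 1 (0.089), against 0.313 without ND 3. The macrophage (mean 0.03, adjusted p = 0.73), inflammatory (mean 0.02, adjusted p = 0.61) and lysosome (mean -0.01, adjusted p = 0.88) lists were not called. Ccl2 (0.28), Lep (0.12), Adipoq (0.01), Scd1 (0.05), Pparg (-0.02), Npr3 (0.29), Fasn (-0.97) and Mpi (0.18) did not pass. With array quality weights in the limma fit, 105 genes were higher and 181 lower, and without ND 1 an unnamed probe, 1 feature in all, was higher.

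**Figure D4:**
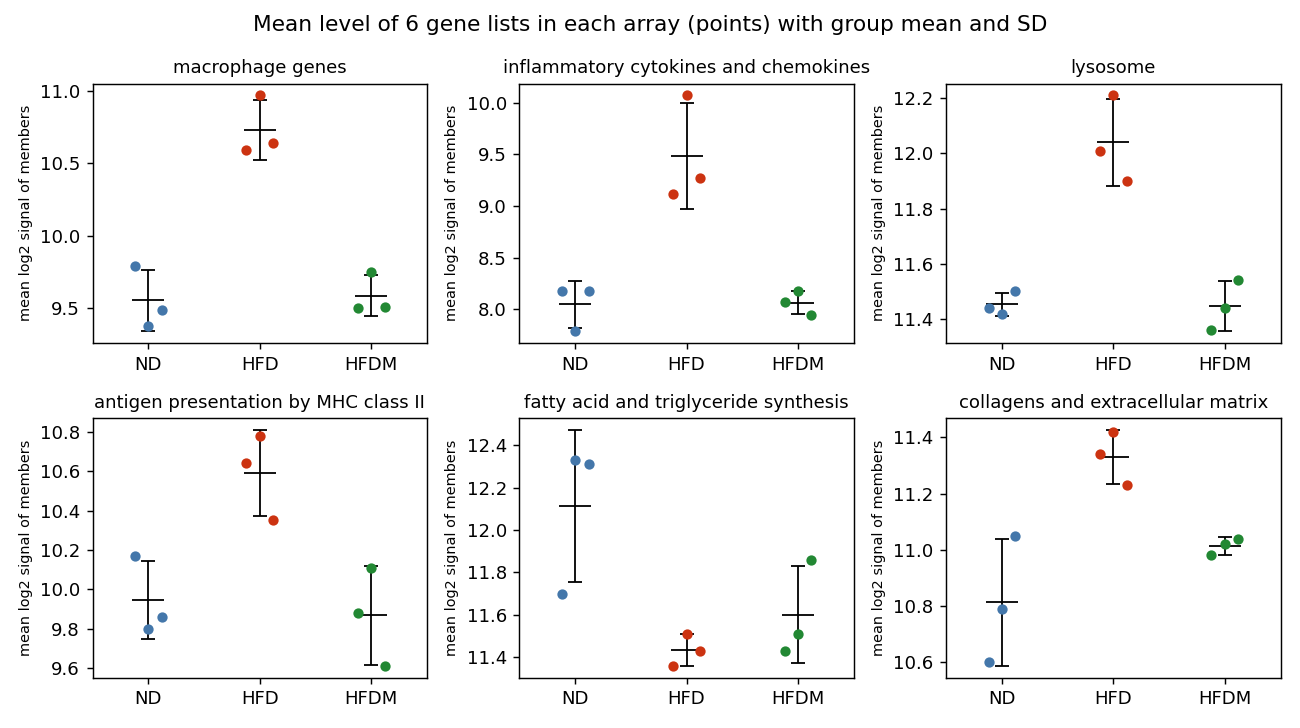
Mean normalized log2 signal of the members of 6 gene lists (vertical axes) in ND, HFD and HFDM, with 1 point per array and the group mean and SD as bars. The macrophage, inflammatory and lysosome lists are highest on the 3 HFD arrays, and fatty acid synthesis is highest in ND on average.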

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

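No test of an explanation was run for the values in this part. Groups of 3 arrays are too small for a search for outlying samples. Among probes outside the comparisons because they were detected on fewer than 3 arrays, those of 2 named genes reached a signal of 1000 on an array of the high fat diet groups while undetected on every ND array. The limit of 1000 was set after the data were seen. The probe of Ucp1, the uncoupling protein of brown fat, had a signal of 5376 on HFDM 3, was also detected on HFD 1 with a signal of 200, and had at most 8.51 on the ND arrays. That of Cck, cholecystokinin, had a signal of 1978 on HFD 2 and at most -12.5 on the ND arrays.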

How the results depend on the processing

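Alternatives on testis transcripts were chosen after the data were seen. Genes and lists are counted here once per comparison, so the same gene or list can count more than once. Of 2210 values of 93 called gene results under alternatives, 1657 stayed called, 553 lost the call and 0 changed sign. Of 740 values of 31 called list results, 630 stayed called. All 31 lost the call with an estimated correlation and 25 lost it with fry. The macrophage, inflammatory and lysosome calls in HFD vs ND and HFDM vs HFD were lost only with an estimated correlation. Causes were not tested unless given. Dim probes near the negative controls limit what can be seen.

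Counts as higher/lower, HFD vs ND then HFDM vs HFD, were 175/59 and 6/49 with median scaling, 710/563 and 594/1015 with array weights, and 144/36 and 95/300 with only 2 groups in the fit. At unadjusted p with 1.5-fold they were 1058/700 and 477/1002 (HFDM vs ND 133/184). With array weights HFDM vs ND had 105/181. HFDM vs HFD had 11/98 with no filter (more genes tested), 57/268 with the strict filter (HFD vs ND 178 lower), 11 higher without trend (71 lower in HFD vs ND) and 17 higher with the authors' table. Same-numbered arrays deviated with r of -0.55 to 0.5, over 0.1 in 3 of 9 pairs. This cannot decide whether the numbers pair mice. The first principal component, with 51.1% of the variance, followed the testis marker mean (r = 0.97), which could hide a pairing. The replicate block gave 130/32, 2/46 and 0 for HFDM vs ND.

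With the testis covariate HFDM vs HFD had 107 lower, and without testis-correlated genes 51 higher (166 lower in HFD vs ND). Without ND 2 and HFDM 1 counts were 153/53 and 6/51. Without the 5 arrays with testis markers HFD vs ND had 318 lower, HFDM vs HFD 38 lower, HFDM vs ND 3/18, and 91.1% had opposite signs. That setting leaves 1 ND, 2 HFD and 1 HFDM array, so the spread comes from HFD 1 and HFD 2 alone, single arrays are assumed to vary like them, and these values say nothing about stability. Leaving out each array gave 42 to 353 higher and 11 to 169 lower in HFD vs ND, 0 to 66 and 4 to 256 in HFDM vs HFD, and 0 to 1 higher in HFDM vs ND.

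Sign changes of genes near 0 were as follows. HFDM vs ND: Adipoq -0.053 and -0.047, Scd1 -0.033 and -0.017 (median scaling, authors' table), Pparg 0.057 (median scaling), Ccl2 -0.51 (weights), Adipoq -0.004 (testis covariate). Weights: Scd1 0.04 in HFD vs ND, Npr3 0.045 and Fasn 0.097 in HFDM vs HFD. Without ND 2 and HFDM 1: Scd1 0.017 and Mpi -0.02 (HFD vs ND), Npr3 0.059, Fasn 0.076 and Mpi -0.077 (HFDM vs HFD), Pparg 0.39 and Mpi -0.097 (HFDM vs ND). Without 5 arrays (1 ND and 1 HFDM array left): Scd1 0.043 and Mpi -0.27 (HFD vs ND), Lep 0.01, Npr3 0.031 and Fasn 0.013 (HFDM vs HFD), Pparg 0.84 and Mpi -0.185 (HFDM vs ND). Leaving out each array: HFD vs ND Mpi -0.15 to 0.168 and Scd1 -0.083 to 0.045, HFDM vs HFD Fasn -0.484 to 0.075, Lep -0.047 to 0.006, Mpi -0.076 to 0.329 and Npr3 -0.097 to 0.081, and HFDM vs ND Adipoq -0.035 to 0.09, Ccl2 0.014 (without ND 2) to 0.783 (without ND 3), Mpi -0.067 to 0.302 and Pparg -0.27 to 0.30. Lists: the amino acid list in HFDM vs ND 0.146 (weights) and 0.016 (without ND 2 and HFDM 1), interferon 0.12 (without 5 arrays, HFDM 2 alone against ND 1 alone), and testis markers 0 in both comparisons with the testis covariate, by construction.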

Other observations

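Tests of testis RNA, of the shared HFD arrays and of adipocyte share were chosen after their results had been seen; the test on epididymal RNA and the splits of the arrays were not, but the rule for reading the epididymal test changed, and its extension to more genes was added, after its value was seen. Further gene groups moved in part. Of 23 glutathione and antioxidant genes, Gsta3 (-1.67 ± 0.22), Gsta4 (-1.75 ± 0.30) and Gpx3 fell and Hmox1, heme oxygenase, rose (1.68 ± 0.31) in HFD vs ND, with 4 lower and 3 higher adjusted over the list alone. The list was not called (camera adjusted p = 0.35), and Gpx3 is named after its value was seen. Of 20 endoplasmic reticulum stress genes, Atf3 (2.34 ± 0.38) and Sel1l (0.84 ± 0.18) rose and Asns fell (-1.01 ± 0.17), in a list that was not called (adjusted p = 0.91). Atf3 changed by -2.29 ± 0.38 in HFDM vs HFD. Fabp5 rose by 1.61 ± 0.34, the only called member of the mature adipocyte list in HFD vs ND. Single arrays held transcripts of their own: liver genes such as Apoa2 on HFD 3, 3.15 log2 units above the next array, and Svs6 of the seminal vesicle on ND 2 (3.74). On ND 1 it was the epithelial Cldn2 (3.71). Over all genes tested, 69 on ND 1 and 155 on HFDM 1 lay more than 4-fold above every other array. The other arrays had at most 11 such genes each (HFD 3), so ND 1 and HFDM 1 stand further apart. Beside Ucp1, HFDM 3 had a signal of 3789 for Cidea and 5448 for Fabp3. These genes were picked after their values were seen.

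Sperm and testis transcripts were high in 5 of the 9 arrays. The 8 markers rose and fell together (median pairwise r of 0.98, lowest 0.93, over arrays that form clusters), which is what RNA of testis or sperm in the dissected fat predicts. Diet as the whole cause is argued against by arrays of the same group that lay up to 7.12 log2 units apart in the marker mean. This range is 2.59 times the largest difference between group means. The ratio cannot exclude a smaller diet effect, since single arrays spread more than means of 3. The 772 genes that follow the markers (r over 0.8) are 5.2% of those tested. RNA from testis or sperm is a candidate source, and when it entered stays open.

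Genes changed by the high fat diet went the other way with mannose. The shared HFD arrays as the whole cause are argued against by at least 98.4% opposite signs with a left-out HFD array, against 49.6 to 55.2% of all genes lower in HFDM than in that array. Testis RNA as the whole cause is argued against by at least 96% opposite signs in the same reading with the testis marker mean as a covariate, against 46.8 to 50.1% of all genes. A lower adipocyte share in HFD that raises every other cell type alike was read in HFD vs ND only. As the whole cause it is argued against by macrophage genes exceeding endothelial markers by 1.20 log2 units there (larger SE 0.28). In HFDM vs HFD, which this test did not read, endothelial markers averaged -0.20, mast cell markers 0.02 and the mature adipocyte list 0.09. A change of adipocyte share beside a change in macrophage genes therefore stays open. An effect of mannose on the response to the diet, a change in macrophage number and a batch shared by the HFD mice stay open and untested, since no batch is given in the sources used here.

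Genes lower in HFD than in ND include Adgrg2, known from epididymal ducts, and epididymal RNA on ND 1 and ND 3 is a possible explanation. The epididymal markers averaged 9.4 on ND 3 but only 6.13 on ND 1, against 6.77 on HFDM 1, so they hardly set ND 1 apart. The 4 genes called lower without ND 2 and HFD 3 were all (100%) higher in ND 2, where the 6 epididymal markers are at log2 signals of 4.83 to 6.28, than in HFD 3, with an exact 95% interval of 39.8 to 100%. Over genes lower at an unadjusted p under 0.01 without ND 2 and 1 HFD array, at least 82.4% were higher in ND 2 than in that array. Of all genes, 47.7 to 51.2% were, which argues against epididymal RNA as the whole cause. ND 2 itself carries transcripts of other tissues, with Svs6 of the seminal vesicle at 11.27 and a testis marker mean of 11.63. The reading therefore covers epididymal RNA only. Counts of calls without 1 ND array cannot decide on epididymal RNA. Genes called lower were 89 without ND 3, 169 without ND 1 and 49 without ND 2. Genes called higher, which epididymal RNA in ND would not add to, kept the same order, with 249, 353 and 158. A part in single genes and an effect of the diet stay open, and genes are not independent.

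Other splits of 6 arrays into 3 and 3 cannot give a share under 0.05 with 10 splits. In HFD vs ND the real split called 405 genes and the highest other 0, so 1 of 10 splits reached that number. In HFDM vs HFD the real split called 202 and the highest other 169, again 1 of 10. That other split sets HFD 1, HFD 2 and HFDM 2 against HFD 3, HFDM 1 and HFDM 3, which follows the testis markers and points to a structure of the samples. With the marker mean as a covariate the real comparison called 22 higher and 107 lower. The other splits were not counted with this covariate, so these counts cannot be set against the 169. In HFDM vs ND the real split called 0 and the highest other 2, so all 10 splits reached it.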
